A study of Mus musculus and Homo sapiens with 10 samples.

How the data were processed

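The series holds ChIP-seq and RNA-seq of embryonic stem (ES) cells of mouse and human. Gm6871, a mouse KRAB zinc finger protein, was tagged with an HA epitope and expressed in the mouse line ES3 for 2 days after doxycycline, and its binding sites were profiled with an anti-HA antibody. KAP1, the corepressor that KRAB zinc finger proteins recruit, was profiled in the wild-type mouse line J1 with an antibody of its own. RNA was sequenced from ES3 cells 4 days after transduction with a lentivirus carrying either an empty hairpin vector or a hairpin against Gm6871, with 2 libraries per group. RNA was also sequenced from the human line H1 at passage 69 after transduction with an empty vector or with hairpins against the DNA methyltransferases (DNMTs), with 1 library per group. Each sample was assigned to its group by its title, and the table columns were matched to samples by name.

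Cytoplasmic RNA was extracted with a DNase step and selected for poly(A), per the labels' protocols. Bowtie 0.12.5 and the builds hg19 and mm9 are named in the submitters' processing notes. How reads with several positions were placed, which annotation release was used and whether strand was kept are not given in the sources used here. The authors deposited RPKM values, that is reads per kilobase of the feature, scaled to a library total, for every RefSeq entry and for single L1 copies longer than 5 kb. L1 (LINE-1) is an autonomous retrotransposon whose subfamilies differ in age. The mouse L1 list held 14949 loci in 36 subfamilies and the human list 9840 loci in 64 subfamilies. The mouse tables also held 8 columns of group means and fold changes by the authors, which were not used here. The authors also deposited 1 peak list per ChIP with a score per peak, and the peak names point to MACS as the caller. The lowest scores were 50.01 for Gm6871 and 50 for KAP1. The scores are the authors' and were used only to rank peaks within a list. Peaks were called on 1 library each. The role of the 2 input samples in the calling is not given in the sources used here, and the inputs were not analysed here.

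Whole reads were worked out from the RPKM values. With the length of each locus, a single total per library turned the values of 100% of the L1 loci into whole numbers within 0.01 reads. With these totals, the smallest whole entry length that gave whole reads in every library was taken for each RefSeq entry kept. One was found for 100% of those with a mean RPKM of at least 0.5 in both organisms. The smallest length can be a fraction of the true one, such as the 78 bp found for MT1X. The reads of such an entry are then understated by the same factor, and its counting interval is too wide. The reads of L1 loci are not affected, since their lengths were given. The search covered lengths up to 120000 bp and allowed 0.0001 reads for mouse and 0.0005 reads for human entries. The library totals were 37198636 and 63023969 reads in the 2 mouse controls, 51415125 and 66050821 in the 2 Gm6871 knockdown libraries, and 100921087 and 92478094 in the human control and knockdown libraries. The reads served for counting intervals and for 1 added test, while the main tests used the deposited values.

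Mouse RefSeq entries were given symbols from a table of the GRCm38.p6 assembly, and 27888 of 36083 entries matched. Entries of a gene were reduced to the entry with the highest mean, which left 30619 genes or unmatched entries. No coordinate of that assembly was used. Human symbols were those in the deposited table. From the human table, 79 symbols of Y-linked genes and XIST were left out before any step, as were 119 symbols that shared an entry with another symbol.

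Mouse groups were compared with limma 3.58.1 in R 4.3.3 on log2(RPKM + pseudocount), with Benjamini-Hochberg adjustment at 0.05. The pseudocount was 0.5 for genes with a mean RPKM of at least 0.5, 0.1 for L1 loci with a mean RPKM of at least 0.1, and 0.01 for the mean over loci of each subfamily with at least 10 loci. A variance trend was used for genes and loci. A log2 difference on this scale understates the change of features with low values. For L1 loci, the estimated prior weight was so large that each locus was tested against a spread shared by loci of like level. With 2 libraries against 2, an exact permutation test of a single value cannot give a p below 0.333. Nothing in the labels states that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The design had assumed that raw counts might be present for a count test. The tables hold RPKM, so limma on log values was used throughout.

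Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it. The lists were pluripotency, primed state, 2-cell-like, primitive endoderm, mesoderm, neuroectoderm, trophectoderm, interferon response, germline, KAP1 and H3K9 machinery, imprinted, p53 response, transposon restriction, feeder fibroblast, ribosomal protein, histone and zinc finger genes. For human cells the lists were the matching ones, with naive state and 8-cell-like genes, endoderm, and X-linked cancer-testis genes in place of primed state, 2-cell-like and primitive endoderm genes. The human libraries had no replicates, so no test across genes was run. Log2 ratios were taken with 0.5 added to each RPKM, and genes with a mean RPKM of at least 1 and a difference of at least 1 were counted. Each list's median was placed among 10000 random lists of the same size, matched on mean RPKM in 20 bins. For L1 subfamilies, the log2 ratio of the mean RPKM over loci was used. Intervals of 95% were exact binomial (Clopper-Pearson) intervals on reads, peaks or L1 copies. None covers more than counting error, since reads without molecular identifiers are not independent molecules. Those on copies treat the copies as independent, although near-identical copies can share reads.

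Peak overlap required at least 1 bp. Shares were compared with 1000 circular shifts of the peaks within their chromosomes, one-sided, so 0.000999 is the smallest p the shifts can give. Shares of loci were compared between subfamilies with Fisher's exact test, two-sided. Peak, locus and gene coordinates were used as the files give them and taken as mm9 for mouse and hg19 for human, with starts counted from 1.

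These comparisons, the gene lists, the thresholds and the rule for naming genes were fixed before the data were examined. The rule named the targets first. For mouse genes it took in each direction the 10 with the largest change past the threshold and no overlap between the groups, filled to 5 by smallest p-value where fewer passed. For human genes it took the 10 with the largest ratio in each direction. From each list past its threshold it took up to 4 members, by p-value in mouse and by size in human. It also took each L1Md subfamily, L1HS to L1PA8, up to 10 other subfamilies per direction and 3 single loci per direction.

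Alternatives covered the pseudocount, the filter on low values, median centring of the libraries, the variance trend, the overlap rule, the higher-scoring peaks, the summary over loci, and leaving out each mouse library in turn, where the lone library of an arm was assumed to vary like the other arm. Others were chosen after seeing the data, among them limma-voom on the whole reads. So were a hypoxia response list for human and mouse cells and a metallothionein list for human cells. A test of genes near Gm6871 peaks was planned and not run, because no gene positions of mm9 were used here.

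The tests were checked on simulated data. Of 100 genes changed by 2 on the log2 scale among 11658 simulated mouse genes, 95 were recovered, against 29 of 100 at a change of 1, and 8 of 11458 unchanged genes were called. Of 100 L1 loci changed by 2 among 3167, 25 were recovered, and 0 of 100 at a change of 1. The noise of genes and loci was drawn independently, with the SD of the fit. Differences shared by many genes between libraries, and loci that spread more than the fit assumed, were therefore not checked. Camera called 2 of 1500 unshifted lists of 20 genes and 100 of 100 lists shifted by 1. Simulated genes varied independently, so lists whose members move together, such as primed state genes (estimated correlation 0.433), were not checked. Overlap counting found 162 of 162 planted overlaps. The human list percentiles lay outside the central 95% for 50 of 50 lists shifted by 1 and for 4 of 50 lists with no shift (8%). The simulated human genes were independent as well. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.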

Results

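The study asked how L1 retrotransposons are kept silent in embryonic stem cells, through the zinc finger protein Gm6871 and its corepressor KAP1 in mouse and through DNA methylation in human. The data comprised 10 samples, of which 2 were ChIP libraries, 2 were their inputs, 4 were mouse RNA-seq libraries and 2 were human RNA-seq libraries. The mouse RNA libraries held between 37198636 and 66050821 reads. Reads in L1 copies longer than 5 kb made up 1.20% and 1.67% of the total in controls 1 and 2, and 1.43% and 1.56% in Gm6871 knockdown libraries 1 and 2. The human control library held 100921087 reads, 0.149% of them in L1 copies, and the DNMT knockdown library held 92478094 reads, 0.230% of them in L1 copies. The ChIP samples and the human RNA samples had no replicates, so their values carry counting error only.

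The first question was which L1 lineages Gm6871 binds. Among the subfamilies with at least 100 copies, Gm6871 peaks lay most often on L1_Mus1, L1Md_F3 and L1Md_F2. Of 3677 L1Md_F2 copies, 161 had a Gm6871 peak (4.38%, 95% interval 3.74 to 5.09%), which was 15.1 times the mean over shifted peaks. L1Md_F3 had 39 bound copies of 721 (5.41%, 17.9 times) and L1_Mus1 had 41 of 704 (5.82%, 20.1 times). The related L1Md_F had 6 bound copies of 268 (2.24%, 8.11 times). L1Md_T and L1Md_A, subfamilies with copies still able to move, had 22 bound copies of 4981 (0.442%) and 8 of 3133 (0.255%). Their enrichment of 1.46 and 0.847 times did not pass the shift test, with adjusted p = 0.161 and 1 over 23 subfamilies. L1Md_Gf had 1 bound copy of 124. The adjusted shift p was 0.00574 for each of L1Md_F2, L1Md_F3, L1_Mus1 and L1Md_F, from the smallest p the shifts can give. L1_Mus3 also passed, with 5 peaks against 1.00 on average in shifted sets (adjusted p = 0.0276).

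Over all L1 copies, 290 of 1277 Gm6871 peaks overlapped L1 (22.7%, 95% interval 20.4 to 25.1%), against 3.47% on average in shifted sets (one-sided permutation by shifts, p = 0.000999). The 287 peaks with their midpoint inside a copy lay at a median distance of 1138 bp from the nearer end of the copy. Of these peaks, 25.4% lay within 1000 bp of an end, against 34.8% for even placement along the copies. The 20 peaks with the highest scores, chosen after the scores were seen, were not on L1, and 17 of them overlapped a KAP1 peak. The inputs were not analysed, so whether these regions give high signal in any library was not tested. The highest, with a score of 3100, was at chromosome 4, 43553666 to 43554551 in mm9, followed by one at chromosome 18, 67979662 to 67980365, with a score of 1129.28. No gene annotation of mm9 was used here, so the neighbouring genes are not given. The median score was 64.64 on L1 and 69.46 off L1. Peaks on repeats depend on how reads with several positions were placed, which is not given in the sources used here.

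**Figure D1:**
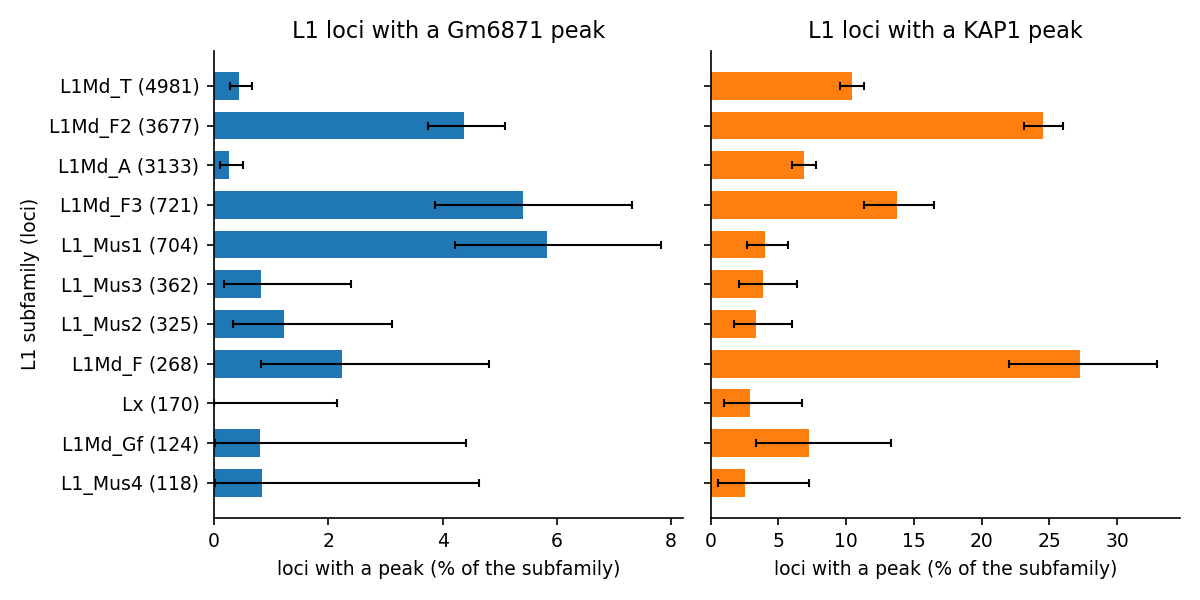
Share of L1 copies with a Gm6871 peak (left) and with a KAP1 peak (right) per mouse L1 subfamily with at least 100 copies, in percent of the copies, with the number of copies in parentheses. Bars are shares and lines are 95% exact binomial intervals. L1Md_F2 stood at 4.38% for Gm6871 and 24.6% for KAP1, and L1_Mus1 at 5.82% and 3.98%.

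KAP1 was compared with Gm6871 because KRAB zinc finger proteins act through it. KAP1 peaks covered 903 of 3677 L1Md_F2 copies (24.6%, 95% interval 23.2 to 26.0%) and 73 of 268 L1Md_F copies (27.2%). Counted as peaks, 932 and 74 lay on these copies, 2.35 and 2.67 times the mean over shifted peaks. L1_Mus1, bound by Gm6871, had a KAP1 peak on 28 of 704 copies (3.98%), and the 31 KAP1 peaks on them were 0.410 times the shifted mean. Of the 41 L1_Mus1 copies with a Gm6871 peak, however, 9 had a KAP1 peak (22.0%). The values were 519 of 4981 copies (10.4%) for L1Md_T, 215 of 3133 (6.86%) for L1Md_A, 99 of 721 (13.7%) for L1Md_F3 and 9 of 124 (7.26%) for L1Md_Gf. The adjusted shift p was 0.0115 for L1Md_F2 and L1Md_F and 0.153 for L1Md_F3. Of the 288 L1 copies with a Gm6871 peak, 104 also had a KAP1 peak (36.1%), against 12.2% of the other copies (Fisher's exact test, two-sided, odds ratio 4.07, p = 7.17e-25). Among L1Md_F2 copies alone, 67 of 161 bound copies had one (41.6%), against 23.8% of the others (Fisher's exact test, odds ratio 2.28, p = 1.26e-06). A KAP1 peak was counted anywhere in the copy, so it need not overlap the Gm6871 peak, unlike in the counts by peaks below.

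By peaks, 297 of 1277 Gm6871 peaks overlapped a KAP1 peak (23.3%), against 2.48% on average and at most 4.23% in shifted sets (permutation by shifts, p = 0.000999). The shifts place peaks anywhere along a chromosome and are not matched on how well reads can be placed or on background signal. Shared binding is thus not told apart from shared background. Peaks off L1 shared more often with KAP1 than peaks on L1, at 253 of 987 (25.6%) against 44 of 290 (15.2%, Fisher's exact test, two-sided, p = 0.000145). Of 45049 KAP1 peaks, 1930 lay on L1 (4.28%, 95% interval 4.10 to 4.48%), against 3.68% in shifted sets (permutation by shifts, p = 0.000999). The ChIP libraries came from different lines, ES3 and J1, and Gm6871 was expressed from a vector. The name of the KAP1 list hints at uniquely placed reads, which would leave fewer KAP1 peaks on near-identical repeats, so KAP1 shares on and off L1 are not strictly comparable.

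The Gm6871 knockdown was meant to show what this protein does to L1 expression. The level of Gm6871 itself was not analysed here, because 0 entries of the RNA table matched its 2 reference transcripts, so the knockdown was not checked. None of the L1 subfamilies passed the test. L1Md_F2 stood at a mean RPKM of 0.0899 ± 0.00818 (SD, n = 2) in controls and 0.101 ± 0.0139 (SD, n = 2) in the knockdown, a log2 difference of 0.14. The difference was 0.083 without the called single copies given below, a setting chosen after seeing the data. L1Md_F3 differed by 0.19, L1Md_F by 0.09, L1Md_Gf by 0.20 and L1Md_T by 0.18 on the log2 scale, and L1Md_A by -0.02. L1Md_T ranged more within the controls, at 0.0552 and 0.176, than between the groups, where the knockdown libraries had 0.102 and 0.129. The 10 other subfamilies with the smallest p among those higher in the knockdown lay between 0.07 (L1VL4) and 0.27 (L1VL1), while Lx2 was at -0.13 and L1_Mus2 at -0.14. By limma, 0 of 23 subfamilies had an adjusted p under 0.05 and 0 an unadjusted p under 0.05, with a lowest adjusted p of 0.881. Voom on the whole reads, chosen after seeing the data, called 0 as well. Without control 2, L1Md_Gf (0.96) and L1Md_T (0.94) passed with an adjusted p of 0.00157 in limma, and without control 1 they turned to -0.55 and -0.58.

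Of 3167 single L1 copies, 3 were called higher in the knockdown by limma and 0 lower. They were an L1Md_F2 copy at chromosome 1, 46127905 to 46134327 (log2 difference 1.81, SE 0.29, adjusted p = 1.4e-06), an L1Md_T copy at chromosome 13, 9831267 to 9837911 (1.53, SE 0.35, adjusted p = 0.0162), and an L1Md_F2 copy at chromosome 1, 102073553 to 102078935 (1.51, SE 0.36, adjusted p = 0.0367). The first had an RPKM of 8.61 and 2.33 in the controls and 7.32 and 34.9 in the knockdown libraries. None of the 3 had a Gm6871 peak, and the L1Md_T copy had a KAP1 peak. Rn28s1, the entry of 28S ribosomal RNA, looked at after these values were seen, stood at 263 and 66.2 RPKM in the controls and at 209 and 1128 in the knockdown libraries. Over the 4 libraries the 3 copies were at 3.09 to 3.52%, 0.878 to 1.22% and 0.591 to 0.949% of the Rn28s1 level. After subtracting the log2 level of Rn28s1, the differences of the 3 copies were -0.05, -0.29 and -0.28, against 1.83, 1.60 and 1.60 before. In all, 5 copies had an unadjusted p under 0.05, where 158 would be expected by chance. The lowest p-values for a lower level, none of which passed, were those of an L1Md_A copy at chromosome 14, 44040285 (-0.93), an Lx2 copy at chromosome 13, 33209256 (-0.48), and an L1Md_T copy at chromosome 1, 77933206 (-0.58), each with an adjusted p of 1.00. Without control 1 the L1Md_A and this L1Md_T copy were called lower (-2.09 and -1.26, limma adjusted p = 3.15e-16 and 0.000106). Without knockdown library 2 the differences of the 3 copies were 0.69, 0.38 and 0.52 and the count was 0, without control 1 it was 19 (3 higher and 16 lower), and without control 2 it was 1567 (1565 higher and 2 lower) with 0 of the 3 copies among them, which were then at 0.89, 0.74 and 0.80. Their differences were 2.73, 2.31 and 2.23 without control 1 and 2.93, 2.67 and 2.502 without knockdown library 1. The count was 0 after median centring, where the differences of the 3 copies were 1.75, 1.47 and 1.45. It was also 0 without a variance trend or at a mean RPKM of at least 0.5, with unmoved differences of 1.81, 1.53 and 1.51, and 1 with a pseudocount of 0.5 (1.71, 1.32 and 1.25). With no filter it was 3, none of them shared, and the differences were unmoved.

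**Figure D2:**
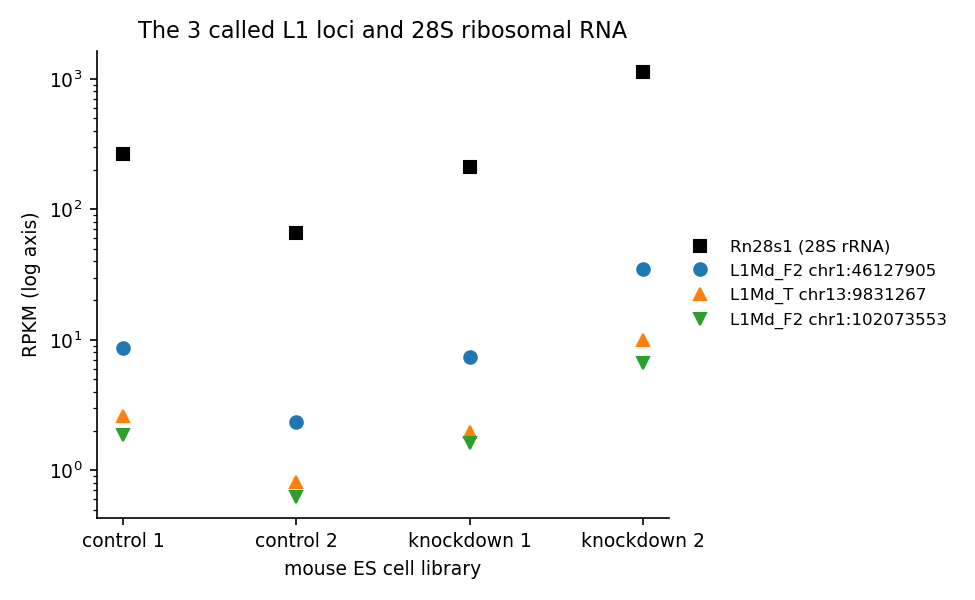
RPKM of the 3 called L1 copies and of the 28S ribosomal RNA entry Rn28s1 in each of the 4 mouse RNA libraries, on a log axis, with 1 point per library. All 4 features were lowest in control 2 and highest in knockdown 2, where Rn28s1 reached 1128 RPKM.

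The copies bound by Gm6871 were compared with the others to join binding and expression. The 39 tested copies with a Gm6871 peak had a mean log2 difference of 0.15, against 0.08 for the 3128 others, and 31 of the 39 were above 0, beside 2184 of all 3167 tested copies. Camera with the preset correlation gave p = 0.00833 for this difference of 0.08, from limma. The call was lost with an estimated correlation (p = 0.534 with an estimated correlation). Bound copies were already higher than the others in each library, by 0.58 and 0.19 in the controls and 0.41 and 0.52 in the knockdown libraries. Without control 2 the difference turned to -0.12 and passed in this opposite direction, and without knockdown library 2 it was 0.020 and did not pass. It was 0.27 without control 1 and 0.13 without knockdown library 1, and both passed. None of these 3 calls held with an estimated correlation in the same fits (limma camera p = 0.345 to 0.419). For the 18 copies with both a Gm6871 and a KAP1 peak the difference was 0.11 (camera p = 0.0144 from limma, and p = 0.504 with an estimated correlation), and for the 381 with a KAP1 peak 0.0091. With no filter on low values, a setting chosen after seeing the data, the difference over 288 bound copies was 0.019 and did not pass.

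No RefSeq gene changed with the Gm6871 knockdown past the threshold. By limma, 0 of 11658 genes had an adjusted p under 0.05, and 223 had an unadjusted p under 0.05, where 583 would be expected by chance. Voom called 0, with 250 at an unadjusted p under 0.05. The 5 genes with the smallest p among those higher in the knockdown did not pass (limma, adjusted p = 0.997 each). They were Ttll6, a tubulin polyglutamylase, at 3.62 ± 0.372 against 8.98 ± 0.891 RPKM (SD, n = 2), Npl, a lyase of sialic acid, at 11.9 against 21.4, Cyp11a1, the cholesterol side-chain cleavage enzyme, at 0.437 against 1.44, the small nucleolar RNA Snord15b at 1.55 against 3.56, and the entry NM_001100608 at 0.199 against 1.38. The 5 lowest were Plekha3, a phosphoinositide-binding Golgi protein, at 17.0 ± 0.855 against 7.85 ± 0.318 RPKM, Rnaseh2c, a subunit of ribonuclease H2, at 43.2 against 23.3, Haus4, a subunit of the augmin complex of the spindle, at 44.5 against 22.1, the kinase Riok3 at 57.8 against 32.5, and the ephrin ligand Efnb2 at 9.94 against 3.15. These did not pass either (adjusted p = 0.997).

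Among the gene lists, primed state genes and primitive endoderm genes were lower in the knockdown by camera with the preset correlation (adjusted p = 0.0125 and 0.0163). Both calls were lost when the correlation was estimated (adjusted p = 0.949 with an estimated correlation for each). Of 14 primed state genes 10 were below 0, with a median of -0.50. They included the DNA methyltransferase Dnmt3b (-0.91), the Wnt effector Lef1 (-0.54), the Wnt modulator Sfrp2 (-0.60) and the POU factor Pou3f1 (-0.97). The keratins Krt8 (0.51) and Krt18 (0.35) and the claudin Cldn6 (0.56) of the same list, picked after their values were seen, were above 0. All 10 primitive endoderm genes were below 0, with a median of -0.35, among them the cubilin receptor Cubn (-0.81), the matrix protein Sparc (-0.57), the transcription factor Gata4 (-0.27) and the collagen gene Col4a1 (-0.64). Adjusted over the list alone, 0 of the 14 and 0 of the 10 genes passed. The median of the primed state genes was higher in libraries numbered 1 than in those numbered 2 by 0.75 in the controls and 0.61 in the knockdown. Without control 1 the primed state list turned upward (camera adjusted p = 0.959). Without knockdown library 2 neither list passed (camera adjusted p = 0.217 and 0.182), and without control 2 primitive endoderm did not (0.184). The primed state list had an adjusted p of 9.66e-09 without control 2.

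None of the other lists passed in mouse cells. Transposon restriction genes had a median of -0.0025 and camera adjusted p = 0.751, and 1 of 12, Rnaseh2c, passed adjusted over the list alone. For the other 12 lists that count was 0. Pluripotency genes had a median of 0.03 over 23 genes (camera adjusted p = 0.940). The medians and adjusted p were -0.21 and 0.940 for mesoderm, -0.21 and 0.698 for neuroectoderm, 0.06 and 0.568 for trophectoderm, -0.34 and 0.534 for interferon response, and -0.29 and 0.149 for germline genes. They were -0.07 and 0.231 for KAP1 and H3K9 machinery, -0.09 and 0.730 for imprinted genes, -0.03 and 0.940 for p53 response, and -0.15 and 0.568 for feeder fibroblast genes. They were 0.06 and 0.231 for ribosomal protein genes and 0.08 and 0.149 for zinc finger genes. The camera direction was opposite to the median for pluripotency, mesoderm and p53 response genes, and the p53 mean was 0.0070. Libraries numbered 1 were above those numbered 2 by a median of 1.04 for interferon response and 1.29 for feeder fibroblast genes. With a library left out, camera called germline genes lower (adjusted p = 0.0312 without control 1 and 0.000723 without knockdown library 1) and interferon response genes lower (0.000345 without control 2 and 0.0334 without knockdown library 1). It also called zinc finger genes higher (9.57e-06 without control 2 and 0.00543 without knockdown library 1) and feeder fibroblast genes lower (0.0401 without knockdown library 1). These calls used the preset correlation, and with an estimated one in the same fits, chosen after seeing the data, no list was called (lowest camera adjusted p = 0.805), although each fit leaves only 1 residual degree of freedom. These directions were not kept in every such fit. Without knockdown library 2, germline, interferon response, zinc finger and feeder fibroblast genes each pointed the other way. Without control 1, interferon response, zinc finger and feeder fibroblast genes did so as well. The 2-cell-like and histone lists had no tested member.

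In human H1 cells the hairpins were aimed at the DNA methyltransferases. DNMT1, the maintenance enzyme, stood at 24.5 RPKM in the control and 6.95 in the knockdown library (28.4% of control). The de novo enzymes DNMT3B and DNMT3A stood at 181 against 75.9 (41.9%) and 17.9 against 12.2 (67.9%).

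The comparison asked which L1 lineages respond to a loss of these enzymes. L1 subfamilies were higher in the knockdown library the younger they were, from L1HS, the human-specific and still mobile subfamily, to L1PA4. The mean RPKM over 331 L1HS copies was 0.0288 in the control and 0.0970 in the knockdown, a log2 ratio of 1.75 (95% interval of reads 1.71 to 1.80). L1PA2 had a ratio of 1.29 (1.27 to 1.31), L1PA3 of 0.68 (0.66 to 0.70) and L1PA4 of 0.21 (0.18 to 0.24). The older L1PA6, L1PA7 and L1PA8 had ratios of 0.16, 0.01 (-0.03 to 0.07) and 0.20. L1PA5 had a ratio of 0.50, which was 0.06 without its 5 highest copies, and L1PA6 was then at 0.03. By the deposited values the higher level was spread over copies, with 322 of 323 L1HS copies with at least 20 reads above 0 (99.7%, 95% interval 98.3 to 100%), 1043 of 1065 for L1PA2, 1189 of 1386 for L1PA3, 392 of 659 for L1PA4 and 64 of 122 for L1PA7. Near-identical copies can share reads, so the values of single young copies and this spread over them are uncertain.

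Of 35 human subfamilies, 34 had a ratio, of which 8 were higher by at least 1 and 0 lower. L1MA9 had no ratio, with 7 reads in the control and 0 in the knockdown library (95% interval up to -0.40). Besides L1HS and L1PA2 these were L1M1, L1PA15, L1MA8, L1PA14, L1PB2 and L1MA2. L1M1 had the largest ratio (5.20), which rested on a copy at chromosome 3, 145091429 to 145097168 in hg19, at 0.199 RPKM in the control and 11.8 in the knockdown. L1PA15 (2.63) rested on a copy at chromosome 3, 154951845 to 154958485, at 0.0597 and 1.23 RPKM. Without the 5 highest copies the ratios of L1M1, L1PA15, L1PA14, L1PB2 and L1MA2 were -0.34, 0.40, -0.46, -0.0095 and 0.38. L1MA8 had 4 and 15 reads. L1MA6 (0.86, 95% interval of reads -0.55 to 2.30), L1M2 (0.71, -0.42 to 1.90), L1PB4 (0.66, 0.27 to 1.09) and L1MC1 (0.63, -0.14 to 1.28) followed. The lowest were L1PA12 (-0.88, 95% interval -1.74 to 0.03) and L1MA5 (-0.62, -1.06 to -0.15), then L1P3 (-0.32), L1MA3 (-0.23), L1PB3 (-0.08) and L1PA13 (-0.03), whose intervals include 0. Without the 5 highest copies L1PA12 turned to 0.22, L1PA13 to 1.17, L1MC1 was at 1.47 and L1MA5 at -1.15. Transcripts without a poly(A) tail were measured beside these values, and 28S ribosomal RNA (RNA28S5) had a ratio of -0.04, 18S (RNA18S5) of 0.13 and the signal recognition particle RNA RN7SL1 of -0.96, while histone genes had a median of 1.38.

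**Figure D3:**
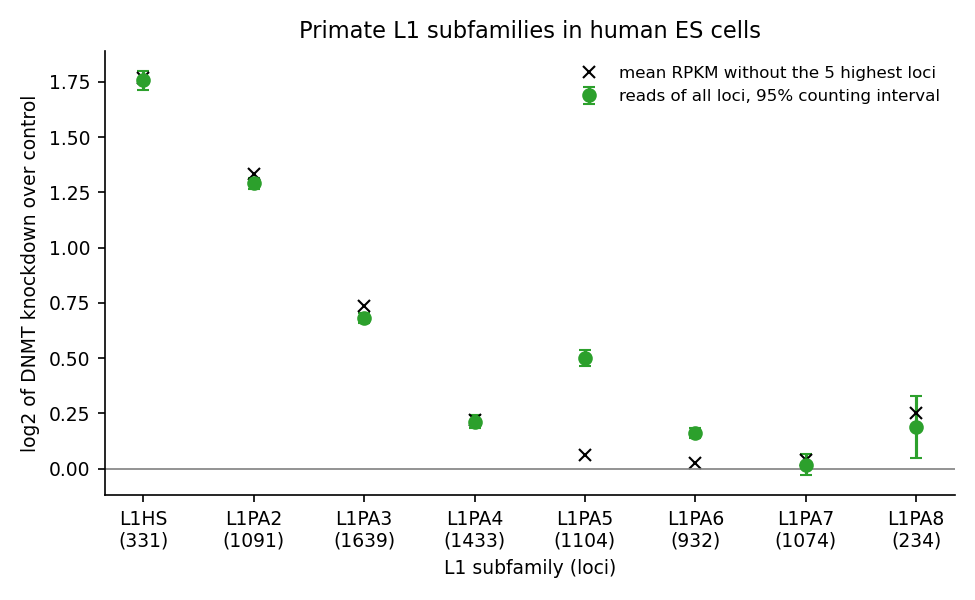
Log2 ratio of DNMT knockdown over control in human ES cells for the L1 subfamilies L1HS to L1PA8, with the number of copies in parentheses and 1 library per condition. Circles are ratios of the reads over all copies relative to the library totals, with 95% counting intervals, and crosses are ratios of the mean RPKM without the 5 highest copies. L1HS stood at 1.76 and L1PA7 at 0.02, and L1PA5 at 0.50 with and 0.06 without its 5 highest copies.

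Of 11740 human genes with a mean RPKM of at least 1, 469 were higher by at least 1 on the log2 scale and 567 lower, with no replicate check. The highest ratios were those of the X-linked VCX3A (0.563 RPKM in the control and 68.8 in the knockdown, a log2 ratio of 6.03), VCX2 (0.291 and 49.7), VCX (0.518 and 57.9) and VCX3B (0.419 and 38.2), DPPA5, an RNA-binding protein of pluripotent cells (0.555 and 52.7), the cancer-testis antigens MAGEB2 (0.0791 and 20.2) and MAGEA6 (0.431 and 29.0), and RHOXF2, a homeobox gene of germ cells (0.107 and 18.5). GAGE2E had 0 reads in the control and 783 in the knockdown, at least 285-fold higher over a floor of 3 reads. GAGE13 had 1 and 814 reads, a log2 ratio of 5.05 on the scale of the other genes, with 0.5 added to each RPKM. Its ratio of reads with nothing added was 9.79 on the log2 scale (95% interval 7.31 to 15.1). VCX and GAGE genes are families of near-identical copies, so their single values are uncertain.

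The lowest ratios belonged to SLC16A3, a lactate transporter (11.2 and 0.191 RPKM, a log2 ratio of -4.08), BNIP3, a receptor of mitophagy (150 and 9.64), and the metallothioneins MT1E (68.2 and 4.50) and MT1G (184 and 20.1). The others were SMOC2, a matrix protein (6.92 and 0.108), the collagen gene COL9A3 (16.2 and 0.936), GAS6, a ligand of TAM receptors (17.6 and 1.18), CDKN1C, an imprinted inhibitor of the cell cycle (10.6 and 0.597), the autophagy gene MAP1LC3C (11.7 and 0.880), and the transcription factor SOX21 (6.87 and 0.362). With a mean RPKM of at least 5, 225 of 7140 genes were higher and 247 lower.

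Germline genes and X-linked cancer-testis genes were higher in the knockdown as groups. Of 9 germline genes 7 were higher by at least 1, with a median of 2.99 at percentile 100 of random lists. They included DAZL, an RNA-binding protein of germ cells (2.90 and 91.2 RPKM), TUBA3D, a testis tubulin (0.343 and 17.8), MAEL, a piRNA factor (0.126 and 11.4), and TEX11, a meiotic gene (0.438 and 8.40). Of 27 genes taken by name as cancer-testis genes, 26 were higher by at least 1, with a median of 4.41 (percentile 100), or 4.44 with the 3 genes at 0 reads set at their bound over 3 reads. MAGEB2, GAGE2E, GAGE13 and MAGEA6 led this list. Some members are near-identical copies with the same reads, such as CTAG1A and CTAG1B (5 in the control and 796 in the knockdown for each). The count, median and percentile therefore weigh some signals more than once. The exception, named after its values were seen, was SSX2IP (4.45 and 6.66), which its symbol alone brought into the list. Histone genes were above 0 in 21 of 21 cases and higher by at least 1 in 13, with a median of 1.38 (percentile 100). Here too HIST2H2AA3 and HIST2H2AA4 had the same reads (140 in the control and 555 in the knockdown). These 3 lists hold genes that reached the mean RPKM through the knockdown library alone, while members low in both libraries were left out. With no filter, 11 of 27 germline, 38 of 70 cancer-testis and 23 of 69 histone genes were higher by at least 1, with medians of 0.63, 1.24 and 0.69, each at percentile 100. Among them HIST1H2BK stood at 2.40 and 49.6 RPKM, HIST1H4H at 0.185 and 4.89, HIST1H1C at 4.21 and 32.5 and HIST1H2AC at 1.67 and 13.3. Canonical histone messages usually lack a poly(A) tail, and whether the histone RNA counted here had one was not tested.

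Targets of p53 were lower, with 6 of 21 lower by at least 1 and a median of -0.54 (percentile 0). The ribonucleotide reductase subunit RRM2B stood at 29.0 and 9.73 RPKM, the antiproliferative BTG2 at 7.20 and 2.56, the cell cycle inhibitor CDKN1A at 11.5 and 4.49 and the cyclin CCNG1 at 159 and 68.2. Ribosomal protein genes had a median of -0.10 over 80 genes (percentile 0.1), with RPL22L1 at 13.9 and 46.9, RPS26 at 144 and 282, RPS24 at 136 and 68.9, and RPL10L listed at 0 in the control and at 4.37 in the knockdown. The naive state list had 4 measured genes and a median of 1.38 (percentile 99.95), with DPPA5 and DPPA3 (0.314 and 6.79) above 0 and KLF4 (3.05 and 2.17) and TFAP2C (2.89 and 0.691) below 0. Trophectoderm genes had a median of -1.51 over 3 genes (percentile 0.13), with the keratin KRT7 at 11.4 and 2.84, TFAP2C as above and the growth factor PGF at 1.29 and 2.09. Interferon response genes had a median of -0.46 over 9 genes (percentile 1.91), with 4 above 0, and held BST2, a membrane restriction factor (43.1 and 77.3), and lower values for the signal transducer STAT2 (6.22 and 3.45), the regulator IRF7 (2.30 and 1.36) and the modifier ISG15 (9.06 and 6.09). With no filter on low values the naive state, trophectoderm and interferon lists lay at percentiles 85.5, 34.7 and 46.4. The interferon list was also inside the central 95% with a pseudocount of 1, at percentile 3.14.

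The other human lists lay within the central 95% of random lists. Pluripotency genes had a median of -0.12 over 22 genes (percentile 3.86, or 0.42 with no filter) and a mean of 0.19, with 4 higher and 4 lower by at least 1. The medians and percentiles were -0.55 and 8.65 for 3 mesoderm genes, 0.15 and 66.8 for 5 neuroectoderm genes, 0.14 and 82.8 for 21 genes of KAP1 and H3K9 machinery, and -0.08 and 26.7 for 12 imprinted genes. They were 0.11 and 71.1 for 15 transposon restriction genes, -0.13 and 13.6 for 12 feeder fibroblast genes and -0.03 and 60.3 for 362 zinc finger genes. The means of the neuroectoderm (-0.09) and transposon restriction lists (-0.02) had the opposite sign to their medians. The 8-cell-like list had 0 measured genes and the endoderm list 1, and with no filter they lay at percentiles 98.9 and 99.9.

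**Figure D4:**
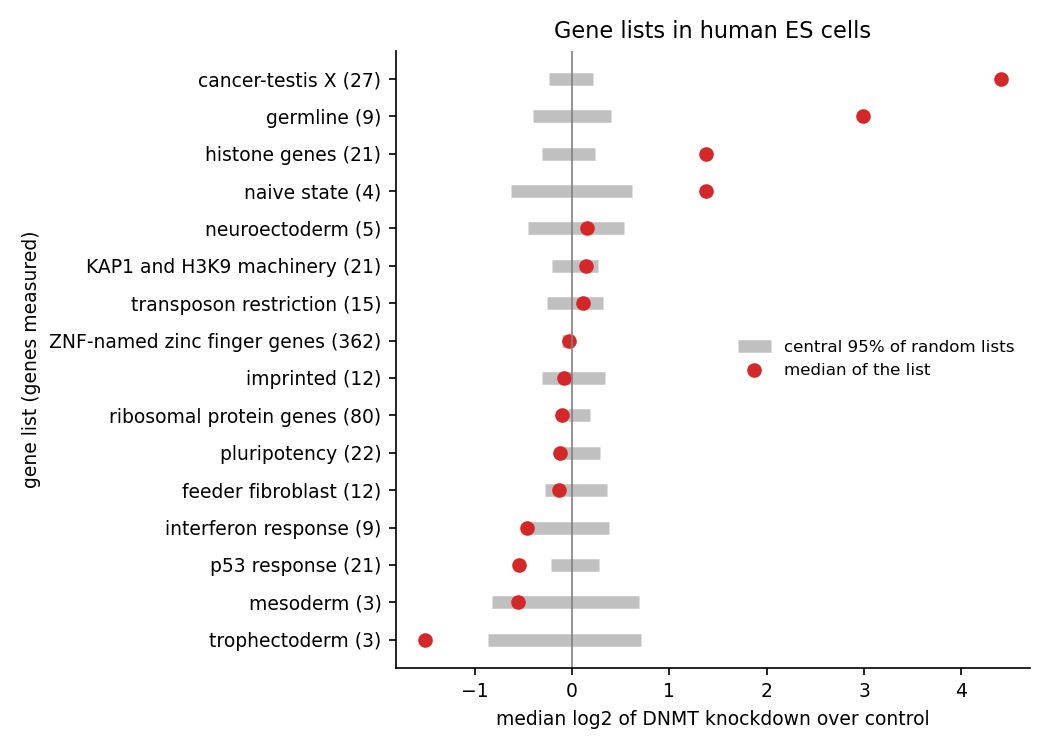
Median log2 ratio of DNMT knockdown over control for each human gene list with at least 3 measured genes, with the number of genes in parentheses and 1 library per condition. Points are list medians and grey bars span the central 95% of 10000 random lists matched on mean RPKM. Cancer-testis genes stood at 4.41, germline genes at 2.99 and p53 targets at -0.54.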

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

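The added alternatives of this part, namely voom, the subfamilies without the called copies, the bound copies with no filter or within L1Md_F2, an estimated correlation under the block or with a library left out, and the human counting interval, were chosen after seeing the data. Counts of mouse genes past the threshold were 0 under each of the 12 alternatives, with lowest adjusted p between 0.407 and 1.00 in limma. The count of called L1 copies was 1 with a pseudocount of 0.5, and 0 at a mean RPKM of at least 0.5, after median centring and with no variance trend, although the differences of the 3 copies stayed at 1.45 to 1.81 in these 3 settings. Leaving out a library gave 0 to 1567, with 16 of 19 lower without control 1 and 1565 of 1567 higher without control 2. The mean log2 level of the 3128 tested copies without a Gm6871 peak was -2.37 in control 1 and -1.48 in control 2. Knockdown libraries 1 and 2 lay between, at -1.94 and -1.76. The mean difference of these copies was therefore -0.36 without control 1 and 0.52 without control 2. What set the controls apart was not tested. Called subfamilies numbered 0 to 2 with a library left out. Leaving out a library gave -0.21 to 0.18 for L1Md_A, -0.11 to 0.28 for L1Md_F, 0.015 to 0.27 for L1Md_F2, -0.067 to 0.44 for L1Md_F3, -0.55 to 0.96 for L1Md_Gf and -0.58 to 0.94 for L1Md_T. It gave -2.09 to 0.22 for the L1Md_A copy on chromosome 14 and -1.26 to 0.10 for the L1Md_T copy at 77933206. As a median over copies L1Md_A was at 0.028. The gene lists called were 0 with an estimated correlation and 0 to 6 with a library left out, where the primed state list had an adjusted p between 9.66e-09 and 0.959 and pointed upward at the latter. With both a library left out and an estimated correlation 0 lists were called, and the primed state list had an adjusted p between 0.805 and 0.989, again upward at the latter. The difference of bound copies was the same 0.077 with an estimated correlation and no longer passed. With a library left out it was -0.12 to 0.27, and it passed as 0.27 and 0.13 upward and as -0.12 downward, while 0.020 did not pass. With an estimated correlation in these fits none passed. Each such fit leaves 1 residual degree of freedom, so this loss decides little. It was 0.019 with no filter, 0.0068 with no filter and a pseudocount of 0.01 and 0.048 within L1Md_F2, and none of these 3 passed. The cause was not tested.

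The mouse replicate numbers are only shared numbers, with 2 pairs and no label that ties them. Libraries with the same number deviated from their group means with a correlation across features of 0.292 for genes, -0.068 for L1 copies and 0.423 for subfamilies. With the replicate number as a block, 4 gene lists were called in place of 2, with interferon response (limma camera adjusted p = 0.0385) and germline genes (0.0415) added at the preset correlation. With an estimated correlation under the block 0 lists were called (lowest camera adjusted p = 0.870 in limma), and the bound copies, at 0.077, did not pass. Under the block the counts of genes (0), L1 copies (3) and subfamilies (0) did not move.

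With the higher-scoring peaks alone, 33.2% of Gm6871 peaks overlapped KAP1, 19.2% overlapped L1, and 4.84% of KAP1 peaks overlapped L1. With at least 50% of the peak covered the KAP1 share on L1 was 3.45%, and with the midpoint inside it was also 3.45%. Each of these shares passed the shift test. Human genes past a difference of 1 numbered 472 at a mean RPKM of at least 5, since fewer genes were tested, and 810 to 1306 otherwise. Human subfamilies past 1 numbered 5 without the 5 highest copies, 4 higher and 1 lower of 31 with a ratio, and 0 as a median over copies, where 0.1 was added to levels far below it. That median was -0.0036 for L1PA5, -0.012 for L1PA6 and -0.0023 for L1PA7, and centring on the gene median put L1PA7 at -0.0040. The named mouse genes kept their direction and stayed short of the threshold in all 40 values with a library left out and all 78 others. They were picked by p-value from these same libraries, and their groups did not overlap. Leaving out a library could therefore not reverse them, and the kept direction is no support. Of the values of named human genes, 78 moved by no more than their 95% counting interval reaches from its estimate, 35 moved by more, and none reversed. A filter leaves the ratio of a kept gene unmoved, and a pseudocount cannot change its sign. Centring moved ratios by only 0.016. The kept direction was thus fixed in advance and is no support for these genes. Genes near Gm6871 peaks were not run, at any distance. In the smallest mouse library, control 1, 553 of 14949 L1 copies had no reads.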

Other observations

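The ratios of the human L1 subfamilies, with and without the 5 highest copies, had been planned. The other tests and genes in this part, and the use of those ratios to weigh explanations, were chosen after the results were seen. In human cells, genes induced by low oxygen were lower in the DNMT knockdown library. Of 29 measured targets of the hypoxia-inducible factor, 27 were below 0 and 15 lower by at least 1, with a median of -1.02 (percentile 0 of random lists). Without SLC16A3 and BNIP3, which had prompted the list, the median was -0.91 over 27 genes. Glycolytic members such as PGK1 (397 and 140 RPKM) and LDHA (236 and 90.2), the prolyl hydroxylase P4HA2 (8.74 and 0.989) and the oxygen sensor EGLN3 (12.0 and 3.74) were lower, while ADM, a vasodilator peptide (23.4 and 45.4), was higher. The mouse hypoxia list differed between the mouse controls too, by a median of 0.79, with 22 of 26 genes higher in control 1. Such a difference between libraries is not excluded in human cells, with 1 library per condition. Metallothionein genes, which bind zinc and copper, were lower in 6 of 6 cases with a median of -2.62, or -1.91 over the 4 genes other than MT1E and MT1G, which had prompted the list. Among them were MT1X (400 and 60.6) and MT2A (74.2 and 29.8). Genes of NODAL signalling stood at 1.14 and 11.6 for NODAL, 2.78 and 31.4 for LEFTY1 and 2.00 and 18.4 for LEFTY2, while their co-receptor TDGF1 stood at 418 and 144. The imprinted long RNA MEG3 stood at 0.0343 and 5.05, and ZFP57, a zinc finger protein that keeps imprints, at 0.159 and 4.98.

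In mouse cells, the largest axis of variation set the libraries numbered 1 apart from those numbered 2 in both groups (50.8% of the variance). Control 1 and knockdown 1 were higher in the keratins Krt8 (199 and 181 RPKM, against 15.6 and 35.6 in control 2 and knockdown 2) and Krt18 (156 and 146, against 14.9 and 26.0). They were also higher in the collagen Col1a1 (9.03 and 9.45, against 0.374 and 0.453), the mesoderm genes T (6.96 and 3.33, against 0.217 and 0.0814) and Hand1 (8.50 and 8.00, against 0.585 and 0.168), and the interferon-induced Gbp2 (53.5 and 23.1, against 0.186 and 0.0245). Differences of at least 1 within both groups were seen for 246 genes, where 39.3 would be shared by independent lists, and 216 of the 246 had the same direction.

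For this difference between libraries numbered 1 and 2, RNA of feeder fibroblasts was weighed first. Col3a1, Dcn, Lum and Postn, abundant in fibroblasts, reached at most 0.580 RPKM in the libraries numbered 1, far below Col1a1, which argues against it as the whole source. A lower share of undifferentiated cells may be a source. The pluripotency genes were lower by a median of only 0.06 in libraries numbered 1 (-0.060 on the log2 scale), which decides nothing, since a small share of other cells would leave them unmoved. Hypoxia response genes differed between libraries numbered 1 and 2 by a median of 0.79 in the controls and -0.21 in the knockdown. In the controls 22 of 26 were higher in library 1, and in the knockdown 7 of 26, so their direction was not shared. Beyond this list and the sources of RNA from other cells, no biological explanation was tested, since the labels give no meaning to the numbers.

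For the 3 L1 copies called higher in the Gm6871 knockdown, reads of ribosomal RNA are a candidate explanation. After subtracting the log2 level of Rn28s1, the largest remaining difference was 0.285 in size, against 1.60 to 1.83 before, so the ribosomal entry moves with nearly the whole difference. The within-group SD of the called copies was at least 3.53 times the SD the test used, so a spread above the shared estimate may also have made the calls. The upper 95% bound of the difference left reached 0.95, so an effect of the knockdown on these copies apart from 28S RNA is not excluded. In 3 of 3 copies the first knockdown library lay between the controls, which goes against a knockdown that moves 28S RNA and the copies together, but 1 library without a measured knockdown does not decide it.

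For the young L1 subfamilies in human cells, the tables argue against 2 technical explanations. The highest ratio of 28S, 18S and 7SL RNA was 0.128, against a general excess of RNA without a poly(A) tail, although histone genes were higher. L1PA7 stood at 0.012, against genomic DNA, which would hold every subfamily. A few dominant source copies stay open, since L1HS kept 1.77 without its 5 highest copies, but these held only 3.75% of the control level and near-identical copies can share reads. A response of young L1 to the loss of DNMTs is also open, as a hypothesis, with 1 library per condition.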
